A study of Homo sapiens with 8 samples.

How the data were processed

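Single-cell RNA-seq of H9 cortical organoids was deposited for 8 samples, 2 Pt/Pt knock-in lines and 2 Hs/Hs control lines at day 60 and at day 90. Per the labels' protocols, libraries were made with the Chromium Single Cell 3' kit. Reads were processed with Cell Ranger 6.1.2 against hg38, per the submitters' processing notes. The clustering, the averaging and the test behind the table are not stated in the labels. How doublets were treated is not stated either, and they could not be looked for, because the table holds no values of single cells.

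The deposited table had a full sheet and a sheet of significant genes for each day. The averages per genotype were used as a score, since the scale of the deposited values is not stated. The log2 fold change of Pt/Pt over Hs/Hs within each cluster was used as the authors gave it. The adjusted p-value was that of the authors, and its adjustment is not stated. The test unit differed from a model on samples, because no counts or values per line could be used. Per the file headers, 4 further columns hold FPKM per line, but the score in each of these deposited columns equalled the genotype average times a factor with an SD of 0.1001. Of 31842 such values found in both sheets of a day with the same average, 0 were equal, so these columns were not used as replicates. In the significant sheet of day 60, 70 adjusted p-values exceeded 1 and 32 absolute log2 fold changes exceeded 20 in the deposited cells, so that sheet was used for membership alone. The sheet followed an adjusted p under 0.05 and an absolute log2 fold change of at least 1.5, which gave 5679 entries in the full sheet at day 60 and 3220 at day 90, against 5679 and 3214 listed. Depth per sample and cell numbers are unknown, so no interval for a level could be given.

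Entries whose gene names had turned into dates (308 at day 60 and 121 at day 90) and repeated entries of a gene in a cluster (12 and 10) were left out. Names matched GENCODE release 29 on GRCh38 for 9985 of 10427 genes at day 60 and 9686 of 10214 at day 90, and coordinates were taken from it. Genes that start after 28 Mb on chromosome 20 were taken as its long arm. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

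Genes were called at the authors' adjusted p-value under 0.05, with pairs of gene and cluster as the unit. Shares of higher calls were given with exact binomial 95% intervals. Recurrent genes were those called one way in at least 18 clusters, and calls were permuted among the genes of each cluster in 100 draws. Fold changes of both days were correlated across genes within clusters of the same number, and overlaps were set beside those of independent lists. The 25 gene lists were fixed before the data were examined and were placed by their median among 10000 random lists of the same size drawn within 20 bins of level, in clusters with at least 3 listed members. Levels of a list in a cluster were the mean of its members' levels, each scaled across clusters, and needed at least 4 listed members, counted among genes listed in at least 10 clusters.

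The log2 fold change was compared with the log2 ratio of the deposited averages, with the averages read as they are and as log2 of 1 plus the value, since the scale is not stated. The median absolute distance was 0.102 and 0.0898 at day 60 and 0.0774 and 0.0534 at day 90 for these readings.

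The rule for named genes, fixed before the data were examined, took for each day the 6 genes called higher and the 6 called lower in the most clusters, the 3 largest changes in each direction in 3 clusters, up to 4 called members of each list, ETV5 and TRA2B, and other called genes of the 3q27 list. Ribosomal protein and mitochondrially encoded genes and genes with clone names were left out of its first parts. The 3 clusters were to be chosen by cell type and number of calls. Without cell type names, they were chosen after the table was seen, by the highest level of the radial glia, intermediate progenitor and pan-neuronal lists. List members reported by their number of clusters were chosen among the named genes after their values were seen, as was MALAT1. Some genes that the rule names are not used here.

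The steps were tested on simulated data. With random fold changes on the day 60 genes, 6.11% of 180 lists of 10 members fell outside the middle 95% (clusters of 4117 genes at the median). With members raised by 0.3, 30% lay above it, and with members raised by 1, 100%. Of 50 genes planted as recurrent among 10427 genes, 50 were found. They were recurrent by construction, so this checks the counting step and not the power to detect weaker recurrence. The most genes reached when the simulated calls were permuted was 0. This does not carry over to lower calls at day 60, where permuted calls of the data reached up to 51 genes.

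Alternatives were limits of 0.25, 0.5 and 1 on the absolute log2 fold change, an adjusted p-value under 0.01 by the authors, the authors' significant sheet, leaving out ribosomal protein and mitochondrially encoded genes, centring on each cluster's median, distinct genes as the unit, Spearman's correlation and the mean of list members. Alternatives that need raw p-values, detection rates or values per line were not run.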

Results

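Human accelerated regions are stretches of the genome that are conserved among other vertebrates and changed quickly in the human lineage. HAR1984 is one such region, and the series title describes a human-specific enhancer that acts on chromosomal contacts and on neurogenesis. Single-cell RNA-seq was run on cortical organoids, which are 3-dimensional cultures that follow early steps of cortical development, grown from the human embryonic stem cell line H9. Organoids in which the human sequence was replaced by the chimpanzee sequence on both alleles (Pt/Pt) were set against organoids that kept the human sequence (Hs/Hs). The 8 samples fell into 4 groups of 2 lines each, Pt/Pt and Hs/Hs at day 60 and at day 90. Each day was 1 batch, so day and batch cannot be told apart.

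The values came from the authors' deposited table, which compared the genotypes within numbered clusters at each day. It gave an average per genotype, a log2 fold change of Pt/Pt over Hs/Hs and an adjusted p. After entries with date-like or repeated gene names were set aside, 147714 pairs of gene and cluster were used at day 60 and 124425 at day 90. They covered 10427 and 10214 genes in 36 clusters at each day. All entries but 3, which were of DGKG, had an absolute log2 fold change of about 0.1 or more. Smaller changes were thus not listed, and the counts, shares, medians and correlations below hold for listed entries alone. Medians of a cluster can jump across 0 for this reason, so centring on them is rough. The depth per sample is unknown, because the table holds no counts. Clusters carried no cell type names and are given by number. Columns headed as values per line equalled the genotype average times a factor with an SD of 0.1001 at all levels, so they gave no replicate error and no value below has one.

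The first question was how far the exchange of this sequence changed expression at day 60, when the organoids hold many progenitor cells and young neurons. A pair was called when the adjusted p in the authors' deposited table was under 0.05. At day 60, 76226 pairs were called, 20564 higher and 55662 lower in Pt/Pt. The share of calls that were higher was 26.98% (exact 95% binomial confidence interval 26.7 to 27.3, for counting error alone). Calls were mostly lower in 34 of 36 clusters. The median fold change of all listed genes, taken over clusters, was -0.18, and after each cluster was centred on its median the share of higher calls was 33.8%. Cluster 2 had the most called genes, 3638, and cluster 10 the fewest, 626.

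The same comparison at day 90, later in neurogenesis, gave fewer calls and another balance. There were 42415 called pairs, 23270 higher and 19145 lower in Pt/Pt. The share that were higher was 54.9% (exact 95% binomial confidence interval 54.4 to 55.3), and 54.3% after centring. Calls were mostly higher in 24 of 36 clusters. Cluster 3 had the most called genes, 2187, and cluster 34 the fewest, 283. Calls with an absolute log2 fold change of at least 1 made up 15.4% at day 60 and 13.2% at day 90.

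**Figure D1:**
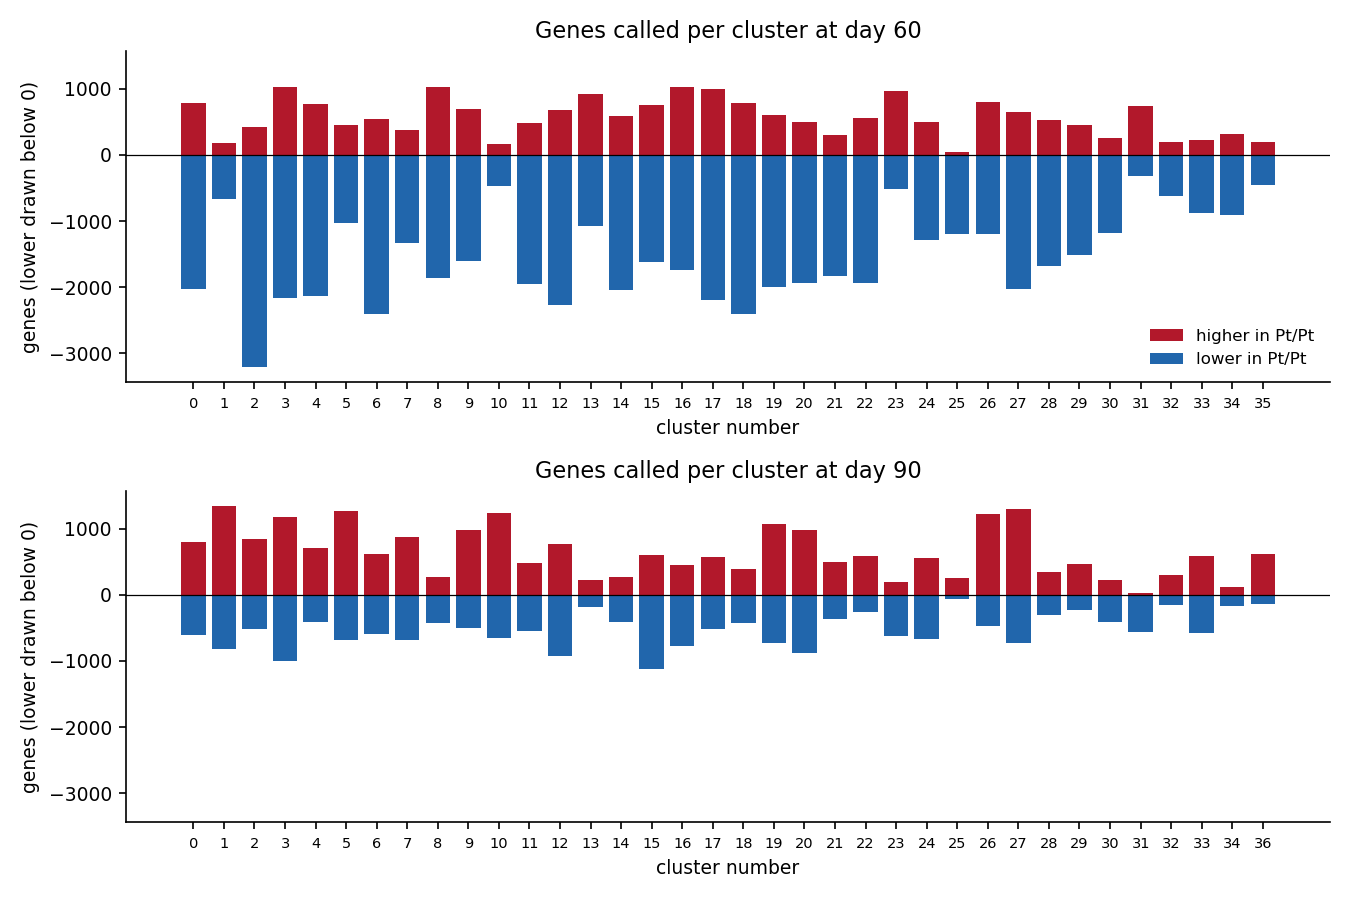
Genes called higher (red, above 0) and lower (blue, below 0) in Pt/Pt in each numbered cluster at day 60 and day 90, as counts. Most bars reach further below 0 at day 60, where 55662 pairs were lower, and not at day 90, where 19145 were.

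The next question concerned the genes nearest to the interval of interest on chromosome 3q27, since an enhancer often acts on neighbouring genes. ETV5 encodes an ETS transcription factor of the FGF pathway, active in cortical progenitors, and lies at 186046308 to 186110318 on chromosome 3 of GRCh38 (GENCODE release 29). TRA2B, at 185915906 to 185938136, encodes a splicing factor. In the authors' deposited table ETV5 was listed in 1 cluster at day 60, cluster 24, where its log2 fold change was -3.48 with an adjusted p of 6.8e-05. At day 90 the authors' deposited table listed ETV5 as lower in clusters 8, 15 and 16, by -2.27, -1.78 and -1.91. Every listed value of ETV5 passed an absolute log2 fold change of 1.5, so clusters with a smaller change, if there were any, may not have been listed.

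TRA2B was called lower in 26 of the 27 clusters that listed it at day 60, with a median log2 fold change of -1.84 in the authors' deposited table. The exception was cluster 35, at 0.53 with an adjusted p of 0.55 by the authors. At day 90 TRA2B was called lower in 13 of 13 clusters, with a median of -1.67. It was among the 4 of 5462 genes listed in at least 10 clusters at day 90 whose every listed value passed an absolute log2 fold change of 1.5, and the 1 gene of them that was called in all its clusters, so clusters with a smaller change, if there were any, were not listed. In 4 of these clusters (18, 20, 22 and 29) the fold change lay below the log2 ratio of the deposited averages, by between -0.42 and -0.64 when the averages were read as log2 values.

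MAP3K13, which encodes a kinase of the JNK pathway and starts at 185282941, was called higher in 32 of 35 clusters at day 60. At day 90 it was called lower in 33 of 35, and the medians in the authors' deposited table were 1.60 at day 60, over the clusters with no average of 0, and -1.42 at day 90. IGF2BP2, an RNA-binding protein gene, was called lower in 30 of 35 clusters at day 60, and at day 90 higher in 9 and lower in 5 of 26. DGKG, a diacylglycerol kinase gene next to ETV5, was called lower in 26 of 27 clusters at day 60 and higher in 8 of 19 at day 90. The day 60 fold changes of DGKG had a median of -0.56 in the authors' deposited table, while the log2 ratio of its deposited averages had a median of -2.68, or -2.97 when they were read as log2 values. At day 90, 9 of the 11 DGKG entries that were not called had an adjusted p out of the order of their sheet in the authors' deposited table, from 0.108 to 0.898 with fold changes of 1.20 to 4.05, where the entries after them had at most 0.00902. The count of 8 rests on these 9 values and would be 17 with the adjusted p of the entries beside them. Among the other genes of the interval, EIF4A2 was called higher in 14 of 28 clusters at day 60 and 7 of 24 at day 90. VPS8 was called lower in 14 of 24, DNAJB11 in 6 of 14 and SENP2 in 4 of 13 at day 60. ST6GAL1 was lower in both of its clusters at day 60, and RFC4 was called higher in 1 of 7.

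**Figure D2:**
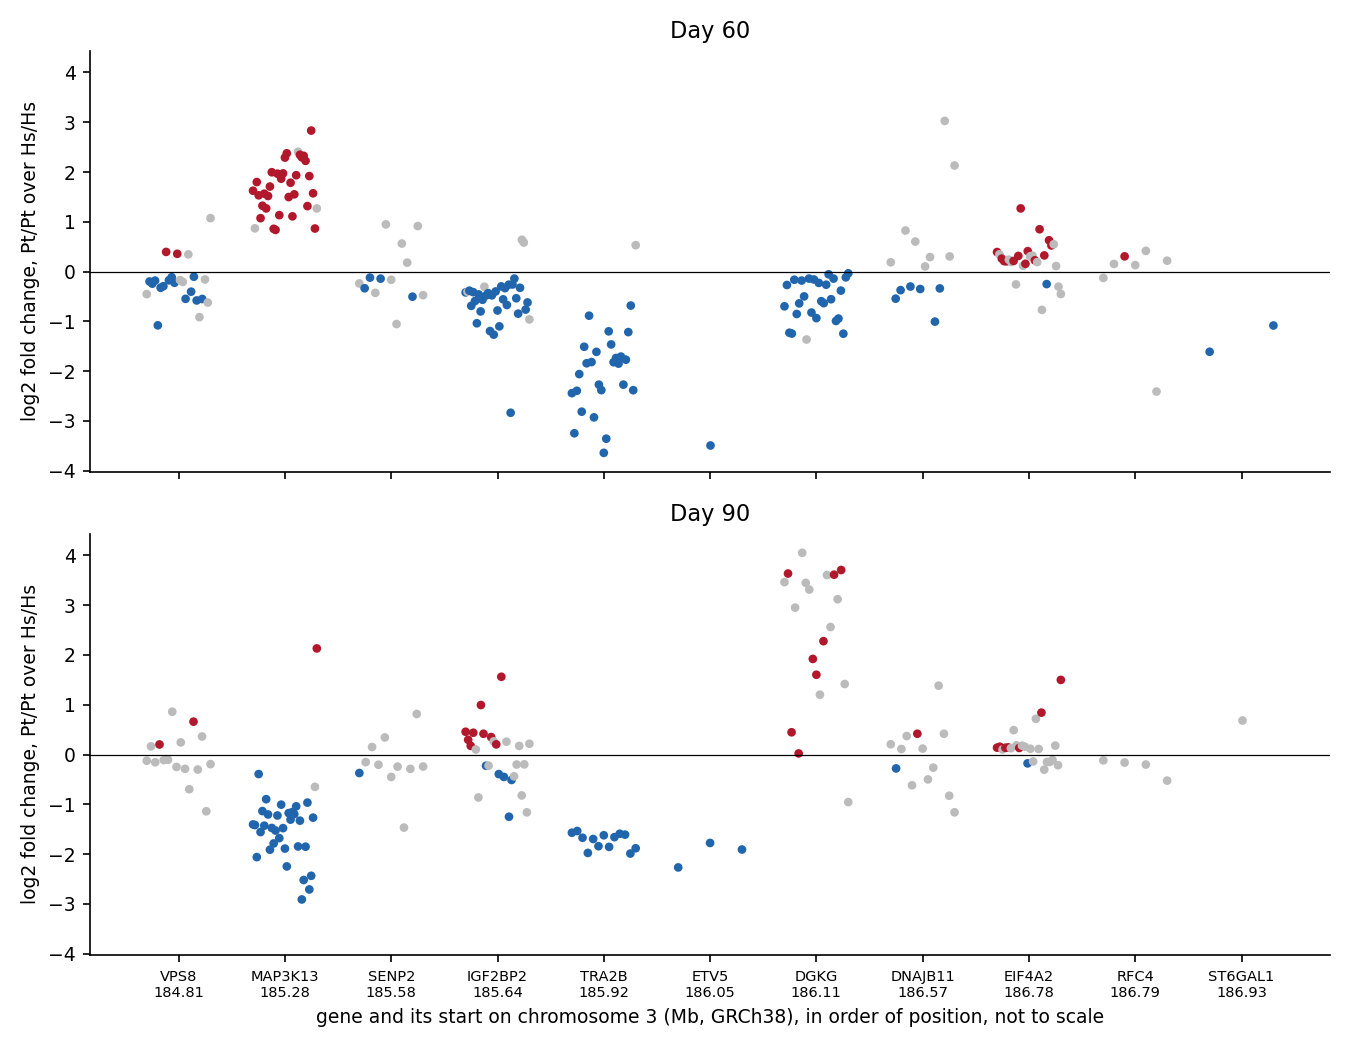
Log2 fold change of Pt/Pt over Hs/Hs (vertical axis) for genes of the interval in order of their start on chromosome 3 (horizontal axis, not to scale), 1 point per cluster, in red (called higher), blue (called lower) or grey (not called). TRA2B lies below 0 at both days except in cluster 35 at day 60, and MAP3K13 changes side between the days.

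The following comparison asked which differences recurred across clusters. At day 60, 251 genes were called higher and 734 lower in at least 18 clusters. When calls were permuted among the genes of each cluster (100 draws), the most genes reached was 0 for higher and 51 for lower. At day 90 the numbers were 138 higher and 70 lower, against 0 and 0 in the draws. Clusters of a day share their libraries, and the mean correlation of fold changes between clusters, across genes, was 0.440 at day 60 and 0.406 at day 90.

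Among the genes with the most calls at day 60, TTR, a thyroid hormone carrier abundant in choroid plexus, was called higher in 33 of 35 clusters, with a median log2 fold change of 1.89 in the authors' deposited table. The ferritin gene FTH1 and the respiratory chain gene ATP5F1E were each higher in 32 clusters, and OST4 and NDUFA4 in 31. BEX3, a small neuronal adaptor on chromosome X, was called lower in 34 of 35 clusters (median -0.81 in the authors' deposited table). SYNE2, which links the nucleus to the cytoskeleton, was lower in 33 clusters, and CASK, PHF6 and AUTS2, genes with known roles in neurodevelopmental disorders, in 32 each. BEX2 was lower in 31.

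At day 90 the genes called higher in the most clusters were BEX3 (34), BEX2 (33), TCEAL7, PHF6 and UFM1 (31 each) and CASK (30). BEX3 had a median log2 fold change of 0.94 and CASK one of 0.99 in the authors' deposited table. EXOC6B, a gene of the exocyst complex, was called lower in 34 of 36 clusters. The splicing factor gene TRA2A was lower in 33 of 35, with a median of -1.18 in the authors' deposited table. NORAD, a long noncoding RNA of genome stability, was lower in 32 clusters, TTR in 31 and the cyclin gene CCND2 in 29. At day 60 NORAD had been called higher in 26 of 31 clusters and CCND2 lower in 18 of 29.

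The clusters for single values were picked after the table was seen, as those in which the radial glia list, the intermediate progenitor list and the pan-neuronal list had the highest level that could be placed. Cluster 2 held the highest radial glia level at both days. There, at day 60, the interneuron transcription factor genes DLX1 and DLX5 had averages of 1.12 and 1.04 in Pt/Pt in the authors' deposited table and were listed at 0 in Hs/Hs. Over all clusters at day 60, DLX1 was called higher in 28 of 28 and DLX5 in 30 of 30, with the Hs/Hs average listed at 0 in each. At day 90 DLX1 was listed in 1 cluster, higher by 1.55 in the authors' deposited table, and DLX5 in 3, called higher in each. The day 60 Pt/Pt averages of DLX1 were 1.12, 1.21 and 0.898 in clusters 2, 11 and 4. Whether this RNA came from the cells of each cluster or from other cells was not tested. DLX1, DLX5, NRXN3 and NNAT were among the 5 of 5724 genes listed in at least 10 clusters at day 60 whose every listed value passed 1.5, so clusters with a smaller change, if there were any, were not listed. NRXN3, a synaptic adhesion gene, was higher in cluster 2 by 9.15 (adjusted p 2e-09) in the authors' deposited table. HS6ST3, a heparan sulphate enzyme gene, was lower by -2.48, TRA2B by -2.39 and the antisense RNA gene GRM7-AS3 by -7.93 in the authors' deposited table.

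At day 90 in cluster 2, NRXN3 had an average of 1.20 in Pt/Pt in the authors' deposited table and was listed at 0 in Hs/Hs, as in all 25 clusters that listed it. DGKG was higher by 3.64 in the authors' deposited table. NNAT, an imprinted neuronal gene, was lower by -4.06 and the ubiquitin ligase gene HECW1 by -2.96 in the authors' deposited table. NNAT was called higher in 8 of 10 clusters at day 60 and lower in 26 of 27 at day 90, and every listed value of NNAT and NRXN3 passed 1.5 at both days, so smaller changes, if there were any, were not listed.

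At day 60 the level of the intermediate progenitor list could be placed only in clusters 0, 6, 11, 15 and 27. Of these, cluster 11 held the highest. EOMES, the marker of these progenitors, was called lower there by -2.47 in the authors' deposited table, although its averages were 0.858 in Pt/Pt and 1.16 in Hs/Hs. At day 90 EOMES was called lower in the same cluster by -4.34, with averages of 0.0739 and 1.11 in the authors' deposited table. In cluster 11 at day 60, DLX1 and DLX5 were again listed at 0 in Hs/Hs, NNAT was higher by 9.10, and DNAJC15 was lower by -5.04 in the authors' deposited table. GRM7-AS3 was listed there at 0 in Pt/Pt. At day 90 the level of that list could be placed in cluster 15 alone, the 1 cluster with at least 4 of its members that were listed in at least 10 clusters, and was not high there (-0.09 SD from the mean of clusters). In cluster 15 SNCG was higher by 5.85 and SIX3 by 5.09, and NNAT was lower by -5.29, ZIC1 by -3.74 and ADCY8 by -2.56 in the authors' deposited table. NRXN3 was listed at 0 in Hs/Hs in cluster 15.

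Cluster 4 held the highest pan-neuronal level at both days. At day 60 CALB2, which encodes calretinin, was higher in it by 2.42, and TRA2B (-2.81), the adhesion gene DSCAM (-2.34) and the phospholipase gene PLCH1 (-2.12) were lower in the authors' deposited table. DLX1 and DLX5 were listed at 0 in Hs/Hs in cluster 4 as well. At day 90 MAF was higher in it by 8.10, while NNAT (-3.24) and G2E3 (-1.65) were lower in the authors' deposited table. NRXN3 was listed at 0 in Hs/Hs.

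Fixed gene lists were used to ask which programmes of cortical development moved with genotype. A list was placed in each cluster among 10000 random lists of the same size and level, and a place outside the middle 95% was counted. At day 60, 66 of 496 placements lay above and 111 below, where 12.4 on each side would come by chance. At day 90, 48 of 465 lay above and 95 below, where 11.6 would. Placements within a day are not independent.

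At day 60 the deep layer neuron list was low in 26 of 35 clusters and high in 0, with a median over clusters of -0.88. The genes BCL11B, which specifies subcerebral projection neurons, and NFIA were called lower in 19 of 20 and 27 of 31 clusters. The pan-neuronal and synaptic list was low in 15 and high in 1 of 36 clusters (median -0.47), and SYT1, which encodes a synaptic calcium sensor, was called lower in 28 of 33. The radial glia list was low in 14 and high in 2 of 29 clusters (median -0.52), with SOX2 called lower in 13 of 17, PAX6 in 13 of 16 and HMGA2 in 17 of 21. The dorsal telencephalon list was high in 18 and low in 2 of 35 clusters. Its members went both ways, as EMX1 was called higher in 20 of 30 clusters, while LHX2 was called lower in 13 of 15. The interneuron and ventral telencephalon list was high in 7 of 7 clusters, with DLX1, DLX5, GAD1 and GAD2 listed at 0 in Hs/Hs wherever they were listed, and without such entries no cluster had enough members. LDHA, a glycolytic enzyme gene, was called higher in 23 of 26 clusters, and the glycolysis and hypoxia list was high in 6 and low in 3 of 36.

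Among the other lists at day 60, the WNT list was low in 8 and high in 1 of 19, the FGF-ERK list low in 5 and high in 3 of 19, and the upper layer list low in 5 and high in 2 of 30. The S phase list was low in 4 of 9 and the G2/M list in 2 of 8. The outer radial glia list was low in 3 of 14, with PTPRZ1 called lower in 25 of 29 clusters. The Notch list was low in 2 of 15, and the intermediate progenitor list was low in 2 and high in 2 of 15. The cholesterol list was high in 8 and low in 3 of 35, and the immediate early and heat shock list was high in 4 and low in 5 of 32. The endoplasmic reticulum stress list was high in 1 and low in 3 of 26. The splicing factor list was high in 2 and low in 1 of 36, and the 3q27 list was high in 1 and low in 4 of 36. The cortical hem and choroid plexus list was high in 2 and low in 1 of 9, the mesenchymal list high in 2 of 4 and the hindbrain, midbrain and retina list high in 2 of 2. Without averages listed at 0, the mesenchymal list kept 3 clusters and the hindbrain, midbrain and retina list none. The metallothionein list was high in 1 and low in 1 of 4, the astrocyte list high in 1 and low in 2 of 3, and the Cajal-Retzius list in 0 of 2.

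At day 90 the radial glia list was low in 15 and high in 2 of 27 clusters (median -0.42), with PAX6 called lower in 13 of 16, SOX9 in 12 of 13 and HES1 in 11 of 17. SOX2, lower in most of its clusters at day 60, was called higher in 4 and lower in 0 of 11. The dorsal telencephalon list was low in 15 of 28 clusters and high in 0 (median -0.42), with LHX2 called lower in 12 of 15. The deep layer list was low in 12 and high in 3 of 32, with FEZF2 called lower in 9 of 9. The upper layer list was low in 9 of 28, with CUX1 called lower in 25 of 29 clusters, while LMO4 was called higher in 10 and lower in 3 of 27. The pan-neuronal list was high in 9 and low in 3 of 36 (median 0.13). Its members went both ways, with 106 calls higher and 75 lower. GAP43, a growth cone gene, was called higher in 24 of 32 clusters, while NEUROD6 was called lower in 9 of 16 and NEUROD2 in 6 of 10. The proneural gene NEUROG2 was called lower in 8 of 8 clusters, and the intermediate progenitor list was low in 3 and high in 1 of 15. LDHA was called lower in 17 of 19, and the glycolysis list was high in 4 and low in 2 of 32.

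For the remaining lists at day 90, the interneuron list was high in 3 of 3 clusters, of which 1 had enough members without averages listed at 0. The immediate early list was high in 7 and low in 2 of 31. The outer radial glia list was high in 4 and low in 1 of 17, and the metallothionein list high in 4 and low in 2 of 12. The Notch list was low in 4 and high in 1 of 14, the WNT list low in 4 of 14 and the G2/M list low in 3 of 7. The S phase list was low in 1 of 8, and the FGF-ERK list was low in 2 and high in 1 of 19. The cholesterol list was high in 4 and low in 3 of 36, the endoplasmic reticulum stress list high in 2 and low in 1 of 20, the splicing list low in 1 of 36 and the 3q27 list low in 5 and high in 1 of 30. The choroid plexus list was low in 3 of 8, the astrocyte list low in 3 and high in 1 of 9, the mesenchymal list high in 1 and low in 1 of 2 and the Cajal-Retzius list in 0 of 1.

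**Figure D3:**
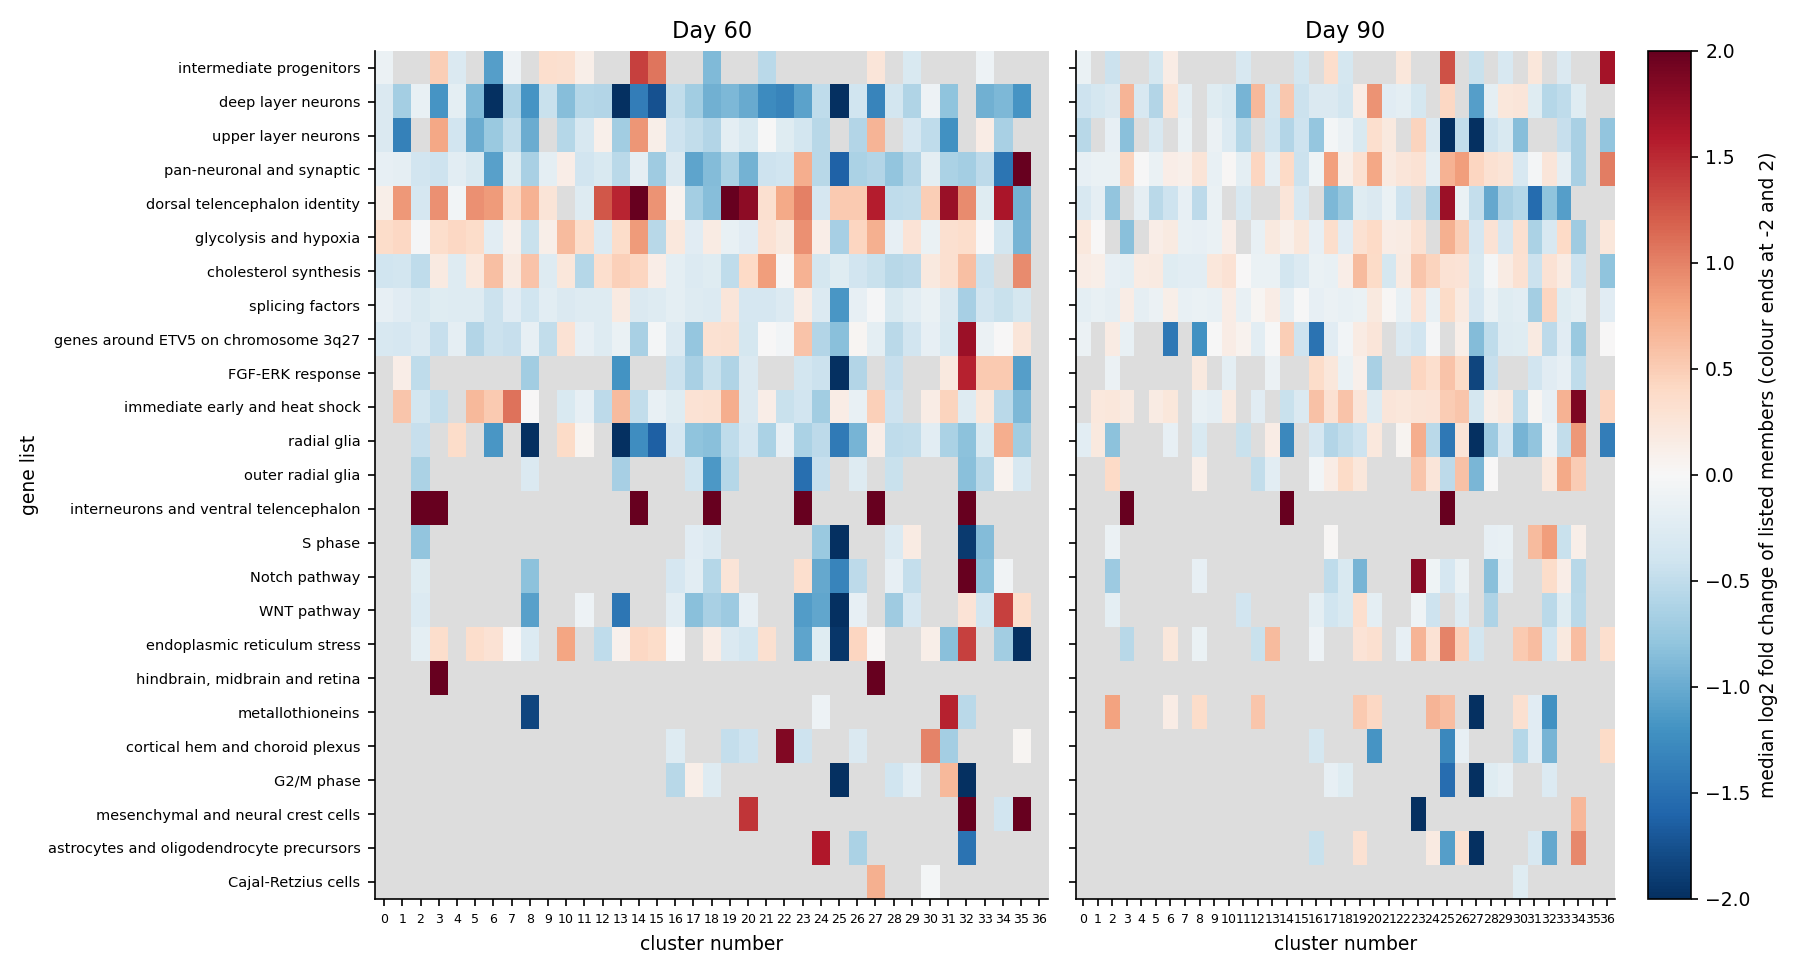
Median log2 fold change of the listed members of each gene list (vertical) in each numbered cluster (horizontal) at both days, with the colour scale ending at -2 and 2 and grey where fewer than 3 members were listed. The deep layer list is below 0 in all clusters tested at day 60, and the dorsal telencephalon list is mostly red at day 60 and blue at day 90.

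The final comparison asked whether the genotype difference of a cluster was alike at both days. The cluster numbers were taken as the same clusters at both days, since the Hs/Hs profile of 32 of 35 shared clusters correlated best with its own number (28 of 35 for Pt/Pt). Across genes, the Pearson correlation of fold changes had a median of -0.09 over the 35 clusters, from -0.72 in cluster 19 to 0.22 in cluster 33, and lay below 0 in 26. The Pt/Pt profile of cluster 19 correlated best with cluster 26 at day 90, while its Hs/Hs profile did so with its own number. Spearman's correlation had a median of -0.05. Genes are not independent replicates, so these values describe the tables. Of 18470 pairs called at both days, 44.4% had the same sign. There were 3491 pairs higher at both days against 2636 for independent lists, and 4715 lower at both days against 5441. The pairs higher and then lower were 3122 against 2161, and those lower and then higher 7142 against 6850.

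There were 96 genes called one way in at least 18 clusters at each day, and 68 of them kept their direction. Of these, 54 were higher at both days, 22 of them ribosomal protein or mitochondrially encoded genes, and 14 were lower at both, among them CUX1, CCND2 and EXOC6B. The other 28 changed direction. MAP3K13, TTR, NORAD and MALAT1 were among the 12 that were higher at day 60 and lower at day 90, and BEX2, BEX3, CASK and PHF6 were among the 16 that were lower and then higher. Of those 16 genes, 12 lie on chromosome X, where 0.8 would be expected from the share among the other 80 (Fisher's exact test, two-sided, p 4.4e-09, computed after the genes were seen). The test counts genes as independent, but they share libraries and some are neighbours. BEX2, TCEAL7 and BEX3 start at 103309346, 103330196 and 103376340 on chromosome X. The p-value therefore does not measure how far such a surplus would recur in other lines. The genes of the long arm of chromosome 20, where NORAD and NNAT lie, were compared with the other autosomal genes after the results were seen. Their median lay above in 33 of 36 clusters at day 60, by 0.41 over clusters, and below in 26 of 36 at day 90, by -0.14. For the short arm the difference was -0.07 and 0.01. Changes under 0.1 were almost never listed, so such medians can jump across 0 and their sizes are rough.

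**Figure D4:**
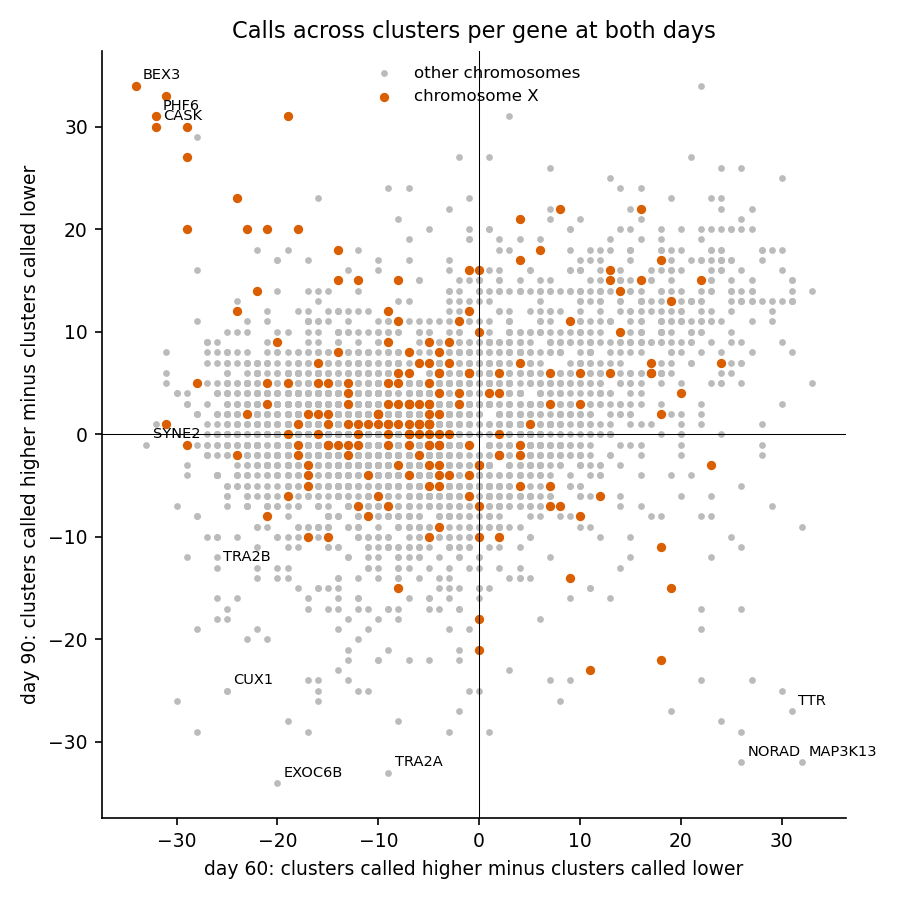
Number of clusters in which a gene was called higher minus the number in which it was called lower, at day 60 (horizontal) and day 90 (vertical), 1 point per gene, with genes of chromosome X in orange. BEX3, CASK and PHF6 lie at the upper left, and MAP3K13, TTR and NORAD at the lower right.

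**Figure D5:**
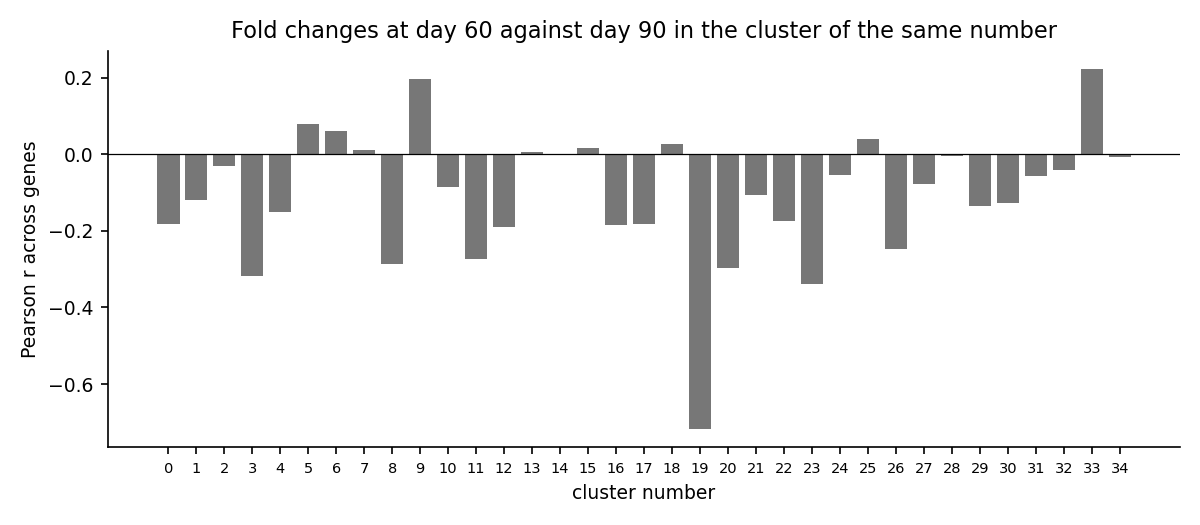
Pearson correlation across genes of the day 60 and day 90 fold changes in each of the 35 clusters with a shared number. The bars run from -0.72 in cluster 19 to 0.22 in cluster 33.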

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

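The alternatives that kept entries with one sign of fold change and averages, left out clusters 23, 25, 27 and 34, or kept clusters whose control profile matched their own number were chosen after seeing the data. A count was taken as about the same within 1.5 times the main count, a share within its 95% interval and a correlation within the 95% interval that its number of genes gives, so a count could fall further than a share. Of 40 alternatives of the comparisons, 21 gave about the same value and 19 moved it, and 0 reversed it. The called pairs, 76226 at day 60 and 42415 at day 90, fell to 34767 and 14359 with an absolute log2 fold change of at least 0.5, to 11765 and 5578 with at least 1, and to 5679 and 3214 in the authors' sheet of significant genes, and to 26669 at day 90 with an adjusted p under 0.01, by construction of the stricter limits. The share of higher calls at day 60 (26.98%) was 33.8% after centring, 28.0% with a fold change of at least 0.25, 24.8% by distinct genes, 25.3% without ribosomal protein and mitochondrially encoded genes and 26.3% with one sign of fold change and averages. At day 90 (54.9%) it was 54.3% after centring, 50.5% with at least 0.25, 50.6% by distinct genes and 54.2% without those genes, so the surplus of higher calls at day 90 depended on small changes and on genes called in many clusters. The pairs with one sign at both days fell from 8206 to 4205 with at least 0.25 and to 4094 with an adjusted p under 0.01. The counts of recurrent genes, added over directions and days so that a gene can count more than once, fell from 1193 to 692 with at least 0.25. The median correlation between days stayed below 0 under all 6 alternatives, from -0.11 to -0.05. Centring cannot move the place of a list among random lists of its cluster, and with the mean of members 323 placements were outside the middle range, against 320. For the median of each list over clusters, about the same meant within 1 SD over clusters. Of 98 such alternatives, 94 gave about the same value, 3 moved it and 1 reversed its sign. The reversed value was that of the astrocyte list at day 90, which went from -0.32 to 0.0400 after centring, and was 0.18 without averages listed at 0. Of 726 alternatives of named genes, 656 gave a number of clusters within 1.5 times the main one, 65 moved it and 5 reversed the direction of most calls. FDFT1 at day 60 kept 6 lower calls with at least 0.25 and 6 after centring, fewer than higher ones, HES5 kept 3 and MT1X 1 after centring, and HERPUD1 at day 90 kept 1 higher call with an adjusted p under 0.01. The cause was not tested. No paired analysis was possible because the table gives comparisons of genotypes and its columns per line could not be used as measurements. For the same reason leaving out each line was not run, nor were the replicate block, Benjamini-Hochberg and Bonferroni adjustment from raw p-values and the filter on detection. The depth is unknown, so what it limits could not be given.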

Other observations

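All tests in this part were chosen only after the results were seen, except the test of low averages for DGKG. On chromosome X, 33 of 149 genes listed in at least 18 clusters were recurrently lower at day 60 (22.1%, against 17.02% of autosomal genes) and 13 recurrently higher (8.72%, against 5.71%), and 22 of 131 were recurrently higher at day 90 (16.8%, against 3.33%) and 4 recurrently lower (3.05%, against 1.72%). Chromosome 20 lay furthest from the other autosomes at day 60, by a median of 0.17 over clusters, and at day 90 it lay below them by -0.04. In the clusters that called a gene at both days, the direction changed in 26 of 26 for NORAD, 31 of 31 for MAP3K13, 16 of 16 for LDHA and 8 of 8 for NNAT, while TRA2B, CUX1 and PAX6 were mostly lower at both.

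Of the 96 recurrent genes, 28 changed direction between the days. An exchange of the genotype labels at 1 day would reverse most lasting differences. Of the 71 such genes that are not ribosomal or mitochondrially encoded, 45 kept their direction. The count weighs small and large changes alike. COX8A kept its direction with median log2 fold changes of 0.51 and 0.26, while MAP3K13 reversed with 1.62 and -1.42. NASP also kept its direction, at -0.58 and -1.03. The count therefore cannot exclude an exchange. Outside these 96 genes, large changes went both ways. TRA2B was called lower in 26 of 27 clusters at day 60 and 13 of 13 at day 90. NRXN3 was called higher in 16 of 16 and 24 of 25. LDHA was called higher in 23 of 26 and then lower in 17 of 19, and NNAT higher in 8 of 10 and then lower in 26 of 27. RNA from other cells would be clearest for genes with a rich source. Of the 28, 2 (TTR and MT-ND6) reached 10 times the level of the median cluster, and only with the averages read as log2 values. As deposited, the highest was 4.82 times. A widely expressed gene could differ in this way without reaching that limit, so the count excludes nothing for the other genes. For TTR RNA from other cells stays open. Its fold change in the cluster with its highest average was 0.55 at day 90 and -0.73 at day 60, opposite to most clusters at each day. The number of such cells per genotype is unknown. A shift of chromosome X as a whole would put its median below the autosomal one at day 60. That held in 16 of 36 clusters. At day 90 the chromosome X median lay above in 31 of 36, by a median of 0.07. The 12 genes of chromosome X that were lower and then higher had 0.76, so such a shift stays open as a part of the day 90 change. A change of some chromosome X genes alone could leave the median in place, so these medians cannot exclude it at either day. For NORAD, which changed by 1.09 and -0.997, a shift of the long arm of chromosome 20 stays open as a part, since the arm lay above the other autosomes in 33 of 36 clusters at day 60 and below in 26 of 36 at day 90, by 0.41 and -0.14. The sizes of these medians, as of those for chromosome X, are rough, since changes under 0.1 were almost never listed. A genotype difference that changes with time, differences between lines, such as a gained copy of that arm, which is known from cultured stem cells, and the batch of each day were not tested and may each contribute. A copy carried alike at both days would by itself move the arm 1 way, and so could not alone give opposite signs. Whether a copy was present at 1 day only is unknown.

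The columns per line deviated from the genotype average by a factor of the same spread at all levels. Measured differences between lines would give 1 value per gene, cluster and line, but 0 of 31842 values were equal in both sheets of a day. The relative SD at the lowest levels was 0.990 times that at the highest, and deviations correlated by at most 0.0109 between sheets, as a random factor of fixed spread would give. How the columns were made is not stated, and no biological explanation was tested.

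Some fold changes lay far from the log2 ratio of the deposited averages. For DGKG at day 60 a scaling of all fold changes would move other genes too, but 1 of 5670 genes, DGKG itself, lay over 10 robust SD away, and low averages would do so in other entries, of which 1.11% had as large a distance. Apart from DGKG, and among entries with averages of at least 0.25 in clusters where the distances had a robust SD under 0.12, 22 entries of 16 genes lay 1.8 to 2.4 below that ratio, against 2 entries from 1.4 to 1.8 below and 2 as far above, and all 22 were called lower, among them EOMES in cluster 11 at day 60, TOP2A, SGO2, G2E3 and EXOC6B. Uneven expression among cells may be part of this, since several of these genes act in the cell cycle, and it stays open because the bands were set after the distances were seen. How these entries arose cannot be told from the table, and no biological explanation was tested.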
